A study of Mus musculus with 2 samples.

How the data were processed

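Total RNA from sorted mouse fetal liver macrophages was hybridised to 2 Affymetrix GeneChip arrays, 1 for wild-type and 1 for c-Maf knockout embryos at E15.5. Cells positive for Mac-1 (CD11b, the product of Itgam) and F4/80 (the product of Adgre1) were sorted by flow cytometry, and biotin-labelled RNA was hybridised, per the labels' protocols. The deposited values are a linear intensity for each probe set, running from 0.0203 to 10606 over both arrays. How the authors summarised, scaled or filtered these intensities is not given in the sources used here; the design text names GeneSpring for the authors' own search for lower genes. The deposited intensities were not at a common level: the median over all probe sets was 4.73 on the wild-type array and 2.98 on the knockout array. Detection calls were not used here.

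Each of the 45101 probe sets had 1 value per array. Of these, 64 were manufacturer's control probe sets. Among the other 45037, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none in the table used here. The symbols of 34741 probe sets were matched through Entrez identifiers to the GRCm38.p6 gene table, and no gene was named from a probe set with several symbols. No genome build applies to the values, so no coordinates are given.

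Values as deposited were raised to a floor at the 50th percentile of all values pooled over both arrays (3.70), and log2 ratios of knockout over wild type were taken from the floored values. Each gene was represented by its probe set with the highest mean deposited signal. Genes at or above the floor on at least 1 array were kept, which left 13479 genes, of which 9238 were at or above it on both arrays. A gene below the floor on 1 array, on the scale of the ratio given, has only a bound, written as at least N-fold. Genes at least 2-fold lower or higher were counted. With 1 array per genotype there were no replicates, so no test, p-value or standard error was possible, and every statement describes these 2 arrays. The spread of log2 ratios between probe sets of the same gene was used as a yardstick: it was 0.65 (SD, from 3985 pairs of probe sets in 1908 genes with a signal of at least 14.8, which is 4 times the floor). It is no replicate error: all probe sets were read on the same 2 arrays, so it leaves out variation between animals, sorts and arrays.

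The knockout array was dimmer by an amount that differed between signal bins. Therefore 5 scalings were examined: values as deposited, equal medians, quantile normalization, log2 ratios centred on the median gene, and scaling to the hybridisation controls. The main setting, values as deposited, and the alternatives other than the hybridisation controls were fixed before the data were examined. Quantile normalization was chosen as the relative scale for the text only after the data were seen, since it removed the overall shift and part of its signal dependence: the medians of 5 signal bins spanned 0.92 log2 units as deposited and 0.52 after it. It is called the level-adjusted ratio, and it assumes that both arrays have the same distribution of signals. Its floor was 3.75. The probe set of each gene was kept as chosen on deposited signals under every scaling; this was also settled after seeing that a new choice after normalization turned a few genes, and the effect of a new choice is given in the closing section. Other alternatives were a floor at the 25th or 65th percentile, the floor as a pseudocount without flooring, the mean over a gene's probe sets, only probe sets without an _x, _s or _a suffix, thresholds of 1.5-, 3- and 4-fold, a brighter signal of at least 4 times the floor, and probe sets counted in place of genes. The last brightness limit was also combined with quantile normalization after the data were seen.

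Before the data were examined, 30 gene lists were fixed, covering macrophage functions, other cell types the sort could hold, cell division, dissociation stress, housekeeping and sex-linked genes. The median log2 ratio of each list was given a percentile among 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays; percentiles refer to values as deposited unless level adjustment is named. Counts of list members at least 2-fold lower or higher are level-adjusted. Of 30 random lists of unrelated genes, 1.5 would lie outside the central 95%. The fixed lists hold related and partly shared genes, so this number is no chance expectation for them. The named genes followed a fixed rule: Maf; the 12 largest deposited falls and 12 largest rises among genes above the floor on both arrays and at least 4 times the floor on the brighter, with all other measured probe sets changed in the same direction; up to 6 bounds each way; up to 4 members per list with the largest absolute ratio; and Vcam1, Adgre1, Itgam, Csf1r, Siglec1 and Il10. Directions in this rule are those of deposited ratios, most of which were falls, so agreement between probe sets says little for a fall. Cd163 was below the floor on both arrays. Other list members are said to have been chosen after their values were seen.

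The calculation was tested on simulated arrays made from the wild-type signals. The observed median shift was applied alike to every probe set, with noise of 0.65 on the log2 scale and 200 genes changed by 2 log2 units. This kept 12912 genes as deposited and 12259 after quantile normalization. The dependence of the shift on signal was not simulated, so the rates below need not hold for the real arrays. As deposited, 100% of lowered and 53% of raised genes were called, and 43.8% of unchanged genes with at least 4 times the floor were called lower. After quantile normalization, 96% and 91% were called, and 7.51% of such unchanged genes were called lower and 7.17% higher. Of 60 simulated lists of 20 genes among 12912, 5% lay outside the central 95% without a shift and 100% lay above the 97.5th percentile when shifted by 1 log2 unit. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.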

Results

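Gene expression was measured in macrophages sorted from the liver of mouse fetuses at E15.5 (days of embryonic development), on 1 array from wild-type and 1 from c-Maf knockout animals of the C57BL/6J strain. c-Maf, encoded by Maf, is a basic leucine zipper transcription factor, and fetal liver macrophages form the centre of the erythroblastic islands in which red cells mature. The design posed the question of which genes are lower in macrophages without c-Maf. The number of arrays limits the precision: no difference below has a replicate check. The only yardstick is the spread of 0.65 log2 units between probe sets of the same gene, which leaves out variation between animals, sorts and arrays.

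Maf was lower on the knockout array. Its brightest probe set had a signal of 47.6 on the wild-type array and 0.219 on the knockout array, which is at least 12.9-fold lower as deposited and at least 8.51-fold lower on the level-adjusted scale. A second Maf probe set went from 21.0 to 0.143, and the other 4 had wild-type signals of at most 5.50. Whether the probes lie in the deleted part of the gene is not known here, so their signals may check the labels only in part. The mean over the Maf probe sets above the floor gave a log2 ratio of -1.51, against -3.69 for the brightest.

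The array as a whole was dimmer in the knockout. Among the 9238 genes above the floor on both arrays the median log2 ratio was -0.93. It ran from -0.33 in the dimmest of 5 equal signal bins to -1.25 in the brightest. This leaves out genes that were below the floor on 1 array, so the fall in the dimmest bin may be understated. The manufacturer's control RNAs did not share this shift: the 18 hybridisation control probe sets had a median log2 ratio of 0.24 (SD 0.087 across probe sets) and the 24 poly-A control probe sets, added before labelling, 0.48 (SD 0.105). The ratio of 3' to 5' signal was 13.3 in wild type and 6.05 in knockout for Actb, and 1.83 and 0.90 for Gapdh. Both were higher in wild type, so the log2 ratio of a gene can depend on where its probes lie. Changes below are therefore given relative to this shift, as level-adjusted log2 ratios after quantile normalization, beside the deposited signals; higher and lower refer to the level-adjusted ratio unless deposited signal is named. This scale kept part of the dependence on signal, with bin medians from 0.40 in the dimmest bin to -0.12 in the brightest, so it favours rises among dim genes.

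**Figure D1:**
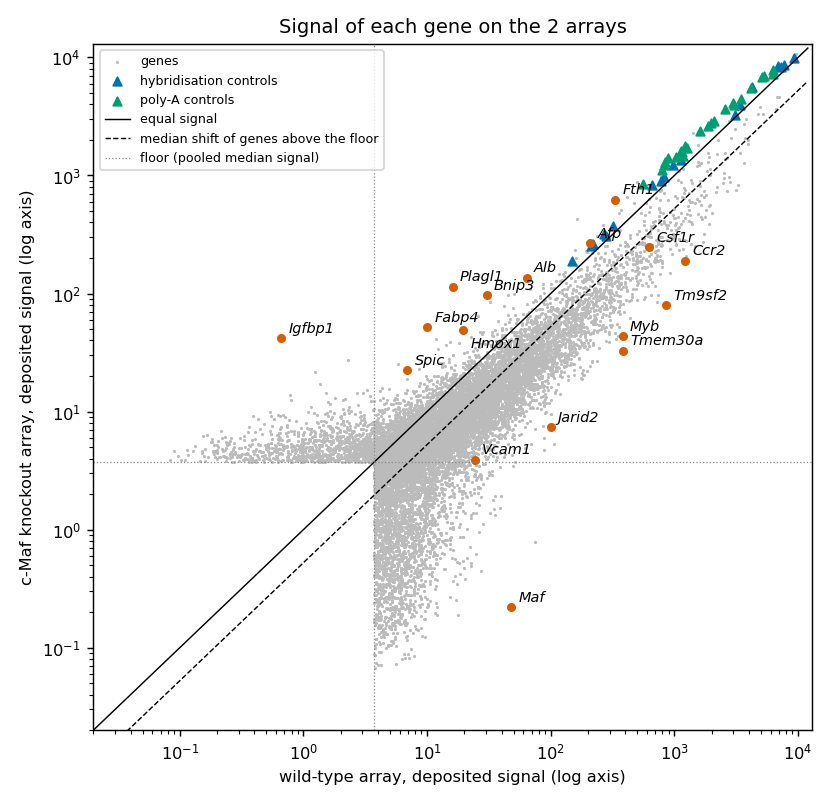
Deposited signal of each gene on the wild-type array (horizontal, log axis) and the knockout array (vertical, log axis); grey points are genes, orange points are named genes and triangles are control probe sets. Most genes lie below the line of equal signal, around the dashed line at a log2 ratio of -0.93, while the hybridisation and poly-A controls lie above it and Maf lies far below it.

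As deposited, 5358 of 13479 genes were at least 2-fold lower and 161 at least 2-fold higher, so 97.1% of the changed genes were lower. That share rested on the scaling. It was 77.5% with equal medians (2167 lower, 630 higher), 52.0% after quantile normalization (1203 lower, 1109 higher), 37.2% with centred ratios (1108 lower, 1869 higher) and 98.5% with the hybridisation controls as reference (6727 lower, 104 higher). All 1203 genes called lower after quantile normalization were also among the 5358. This follows largely from the upward shift that quantile normalization gives most ratios, so it is no agreement between scalings. Of the 1109 called higher, only 161 were also at least 2-fold higher as deposited. Among 5553 genes with a signal of at least 4 times the floor, 664, or 11.96%, were lower and 479, or 8.63%, higher after quantile normalization. The median of bright genes was still -0.17 on that scale, which favours lower calls among them, and how many calls would differ between samples of the same genotype is not known here.

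By deposited ratio, the genes with the largest falls were Jarid2, a cofactor of Polycomb repressive complex 2 (signal 99.8 to 7.34, level-adjusted log2 ratio -2.72), Dnajc14 (69.7 to 5.36, -2.71), and Zfp934 (62.4 to 4.92, -2.69). Tmem30a, a subunit of phospholipid flippases, went from 385 to 32.8 (-2.41), and Tm9sf2 from 850 to 80.0 (-2.38). The others of the 12, ordered here by level-adjusted ratio, were Dapp1 (-2.54), Rfx7 (-2.46), Dlst (-2.43), Dtl (-2.41), Cadm1 (-2.34), Evi2a (-2.33) and Emc1 (-2.33). Genes above the floor in wild type and below the floor in knockout in deposited signal included Ap2a2 (73.9, at least 13.1-fold lower after level adjustment), Mapk13 (49.0, 7.56-fold), Usp42 (39.5, at least 7.12-fold), Il17ra, the interleukin-17 receptor (38.9, at least 7.01-fold), and Ptms (39.1, 6.17-fold). Probe sets of Ap2a2 and of Ptms were not all in the same direction, and another Ap2a2 probe set went from 38.3 to 23.4 (level-adjusted 0.42). Without suffixed probe sets the deposited log2 ratio of Jarid2 was -0.79 and that of Tm9sf2 -0.58, against -3.76 and -3.41. Neither was at least 2-fold lower there. Level-adjusted, these probe sets were at -0.04 for Jarid2 and 0.44 for Tm9sf2, so that of Tm9sf2 went the other way. A further probe set of each was at -0.82 for Jarid2 and -1.88 for Tm9sf2.

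By deposited ratio, the genes with the largest rises, listed with their level-adjusted ratios, were Plagl1, an imprinted zinc finger gene (16.1 to 114, log2 ratio 3.91), Fabp4, a fatty acid binding protein of macrophages, adipocytes and endothelium (10.03 to 51.8, 3.36), and Kank2 (4.28 to 15.98, at least 6.25-fold). The others of the 12 included Bnip3, a mitochondrial protein of mitophagy (30.3 to 97.2, 2.82), Apoa1 (2.67) and Spic (2.63); Apoa1 and Serpina1b belong to the hepatoblast list, whose level-adjusted median was 1.52. Mest, another imprinted gene, went from 32.5 to 84.8 (2.52), and the metallothionein gene Mt2 from 162 to 426 (2.45). Gimap4 (2.49), S100a16 (2.43), Med18 (2.40) and Serpina1b (2.38) completed the 12. Igfbp1, a secreted binder of insulin-like growth factors, was below the floor in wild type and at 41.8 in knockout, at least 16.7-fold higher. Lama5 (at least 11.0-fold), Trib3 (at least 8.52-fold), Trp53i11 (at least 6.66-fold) and Scrt2 (at least 5.96-fold) were the other genes of that kind, and probe sets of Lama5 and of Trib3 were not all in the same direction. The mean over probe sets gave log2 ratios of 0.82 for S100a16 and 0.97 for Lama5, short of 2-fold. Plagl1 rested on 1 suffixed probe set of 3, as the others were below the floor on both arrays. Fabp4, Apoa1, Spic, Gimap4, Serpina1b and S100a16 were also represented by suffixed probe sets.

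Genes of erythroblastic island adhesion included Vcam1, the adhesion molecule by which macrophages bind erythroblast integrin alpha-4 beta-1. Vcam1 was lower on the knockout array, with a signal of 24.4 in wild type and 3.90 in knockout (log2 ratio -2.64 as deposited, -1.76 level-adjusted). The integrin genes Itgb5 (55.7 to 10.6, -1.30) and Itgav (42.0 to 9.21, -1.12) were lower too, although a dim probe set of each went the other way. The mean over Itgav probe sets was -0.66 as deposited, no lower than the -0.93 of the median gene. Cd44 had a level-adjusted ratio of -0.66. Of the 18 measured list members, 3 were at least 2-fold lower, 3 at least 2-fold higher and 12 within 2-fold. The higher members were Klf1, a master regulator of erythroid genes (42.9 to 55.1, 1.53), Siglec1 (5.91 to 8.10, 1.29) and Itgb1, which was slightly lower in deposited signal (96.3 to 93.3, level-adjusted 1.12); Klf1 and Itgb1 were chosen after their values were seen. The list median lay at the 84.3rd percentile of matched random lists. The wider integrin list had 2 of 20 members lower and 1 higher, at the 30.5th percentile, with Itgb2 at -0.68 and Itgal at -0.74.

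Sort and identity markers of macrophages were present on both arrays. Transcripts of other cell types were present too, and some were far brighter. S100a8 of the granulocyte list, chosen after its value was seen, had signals of 4717 in wild type and 3317 in knockout. Hbb-y of the embryonic globin list had 7061 and 4650. Changes on these arrays thus cannot be assigned to macrophages alone. Adgre1, encoding F4/80, had a signal of 71.4 in wild type and 48.1 in knockout, a level-adjusted ratio of 0.60 that is -0.57 in deposited signal. Csf1r, the receptor for colony stimulating factor 1, went from 625 to 248 (-0.24), and Itgam was near the floor on both arrays (5.76 and 3.94). The transcription factor genes Cebpb (208 to 24.2, -1.94) and Irf8 (129 to 26.5, -1.11), the signal-regulatory receptor gene Sirpa (100 to 12.6, -1.88) and Ptprc, encoding CD45 (209 to 45.2, -1.05), were lower; the 2 Cebpb probe sets went in opposite directions. Cd68, Fcgr1, Fcer1g and Aif1, chosen after their values were seen, were at least 2-fold higher after level adjustment, with ratios of 1.43, 1.21, 1.12 and 1.10. Fcer1g and Aif1 were slightly lower in deposited signal. Of 24 measured members, 4 were lower, 4 higher and 16 within 2-fold, at the 90.7th percentile.

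Markers of resident liver macrophages were mixed. Spic, a transcription factor of red pulp and iron-recycling macrophages (6.94 to 22.3, 2.63), and Hmox1, which degrades heme (19.5 to 49.2, 2.42), were higher, while Cfp, encoding properdin, went from 19.5 to below the floor (at least 3.66-fold lower) and Mrc1, the mannose receptor, from 19.8 to 5.72 (-0.87). Of 21 members measured after level adjustment, 5 were higher and 1 lower, at the 92.8th percentile. Among complement, efferocytosis and scavenger genes, 6 of 27 were lower and 4 higher (27.0th percentile). Lrp1, an endocytic receptor of apoptotic cell clearance (55.6 to 6.35, -2.12), and Abca1, a cholesterol exporter (32.5 to 7.05, -1.20), were lower, whereas the complement gene C1qa (16.3 to 30.2, 1.97) and Mfge8, a bridge to apoptotic cells (8.84 to 17.5, 1.95), both chosen after their values were seen, were higher.

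Iron and heme handling genes stood above matched random lists. Of 20 measured members, 5 were at least 2-fold higher, 2 at least 2-fold lower, 11 within 2-fold and 2 known by a bound only. The list median was 0.55 level-adjusted and -0.44 as deposited, at the 99.9th percentile and between 98.9 and 100 under every alternative. Besides Spic (2.63) and Hmox1 (2.42), the biliverdin reductase gene Blvrb (22.5 to 42.8, 2.03), the ferritin heavy chain gene Fth1 (333 to 625, 1.90) and the phagosomal metal transporter gene Slc11a1 (11.5 to 19.9, 1.80), chosen after their values were seen, were higher. The erythroid list, whose cells also express iron and heme genes, lay at the 97.7th percentile, and housekeeping genes stood further above their matched lists as deposited, by 0.82 log2 units against 0.63 for iron and heme genes. Flvcr1, a heme exporter (37.5 to 8.29, -1.13), and Slc11a2 (12.1 to below the floor, at least 2.38-fold) were lower, and Bach1, a heme-sensing repressor, was at -0.43. On the same arrays the hepatoblast genes described below were higher, and they had the highest level-adjusted median of the 30 lists, 1.52.

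Interferon response genes were also high for their signal, with 7 of 28 members at least 2-fold higher, 0 lower and a level-adjusted median of 0.78 (-0.27 as deposited; 99.9th percentile, 99.9 to 100 under every alternative). Rtp4 (25.4 to 38.8, 1.73) and Ifi27l2a (33.3 to 47.2, 1.63), chosen after their values were seen, and Ifit2 (below the floor to 7.82, at least 2.90-fold) were higher, while Irf7 was at -0.80 and Ifi203 at -0.87. Oas2 was 2.10-fold lower as deposited (38.6 to 18.4) and at 0.057 after level adjustment. Of the cytokine, chemokine and inflammatory genes, 7 of 31 were higher and 1 lower, at the 91.4th percentile as deposited and the 99.9th after level adjustment. Csf1 went from 17.0 to below the floor (at least 3.21-fold lower), although its probe sets were not all in the same direction. Ccl24 (9.72 to below the floor, at least 1.95-fold) was next among the falls, and Nfkbia (-0.28) and Il15 (-0.07) were within 2-fold.

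Lysosomal genes had a median of 0.28 level-adjusted and -0.63 as deposited, at the 99.9th percentile, with 2 of 29 members at least 2-fold higher, 1 lower, 24 within 2-fold and 2 known by a bound only. The percentile was 94.4 with probe sets lacking a suffix and 96.9 with means over probe sets, both inside the central 95%. Psap, the prosaposin precursor (457 to 92.6, -1.13), Lamp2 (-0.91), Creg1 (-0.86) and Tcirg1 (-0.80) were its lowest members. Matrix and matrix protease genes had 3 of 20 members higher and 0 lower, with a median of 0.63 level-adjusted and -0.31 as deposited, at the 99.0th percentile but at the 96.6th with the higher floor. Sparc went from 4.91 to 15.6 (2.55), although its probe sets were not all in the same direction and their mean was 0.50 as deposited, while Fn1 (-0.99), Timp3 (-0.61) and Timp2 (-0.49) had ratios below 0. The interferon, cytokine, lysosomal and matrix lists stood high on the same array as the hepatoblast list, with its median of 1.52.

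Monocyte genes had the lowest percentile of the 30 lists as deposited, and were among the lowest level-adjusted. Ccr2, the chemokine receptor of inflammatory monocytes, had a signal of 1212 in wild type and 190 in knockout (-1.74). A dim Ccr2 probe set, however, went from 7.25 to 13.1. The mean over Ccr2 probe sets was -0.91 as deposited, no lower than the -0.93 of the median gene. Klf4 (87.0 to 16.1, -1.29) and Nr4a1 (38.4 to 8.48, -1.12) were lower, F13a1 was at -0.94 (916 to 237), and Plac8 (473 to 586, 1.31), chosen after its value was seen, was higher. Of 13 members, 3 were lower, 2 higher and 8 within 2-fold. Nr4a1 is also an immediate early gene, and that list, which responds to cell dissociation, was low on the same array (0.79th percentile level-adjusted). The median was -1.78 as deposited and -0.74 level-adjusted, at the 0.19th percentile, but at the 24.0th with means over probe sets.

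The position of progenitor and cell division genes rested on the setting. Myb, a transcription factor of hematopoietic progenitors (381 to 43.5, -1.99), Cd34 (58.5 to 11.9, -1.20), Flt3 (19.5 to below the floor, at least 3.65-fold) and Kit (16.9 to below the floor, level-adjusted -1.52) were lower. Of 14 stem and progenitor genes 5 were lower and 1 higher, at the 12.8th percentile as deposited and the 1.19th level-adjusted, but at the 38.4th with the higher floor. Among 37 proliferation genes, 5 were lower and 1 higher, at the 3.25th percentile. The percentile ran from 1.8 to 50.1 over the alternatives, with the highest for probe sets lacking a suffix. The lowest were the replication licensing genes Mcm5 (1173 to 236, -1.36) and Mcm4 (-1.14), Uhrf1 (-1.26) and Cenpe (-1.17). With probe sets lacking a suffix Mcm5 was at -0.68 as deposited. That probe set was at 0.48 level-adjusted, the other way, and a dimmer one was at -0.56. The 8 self-renewal factors, Myb and Klf4 among them, had 2 lower and 0 higher (18.3rd percentile), with Zbtb16 at -0.38 and Ezh2 at -0.25. Immediate early genes, which also respond to cell dissociation, had 4 of 24 lower, namely Egr1 (181 to 20.2, 3.99-fold), Fos (111 to 15.2, -1.74), Jun (-1.34) and Nr4a1 (-1.12), and 2 higher, at the 3.90th percentile as deposited and the 0.79th level-adjusted.

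Hepatoblast genes, which belong to the epithelial cells of the fetal liver, were higher on the knockout array. Of 20 measured members, 14 were at least 2-fold higher after level adjustment and 0 lower, and the median was 0.66 as deposited and 1.52 level-adjusted, at the 100th percentile under every alternative. Apoa1 (6.69 to 22.2, 2.67), Serpina1b (8.62 to 23.1, 2.38), Ambp (4.38 to 13.02, at least 5.05-fold higher) and Fabp1 (below the floor to 14.3, at least 5.57-fold higher) led the list, although another Fabp1 probe set went from 7.43 to 4.52 and the mean over its probe sets was 0.62 as deposited. The abundant hepatoblast transcripts Alb (63.8 to 136), Afp (209 to 268) and Ttr (42.0 to 77.8), chosen after their values were seen, were higher in deposited signal too.

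**Figure D2:**
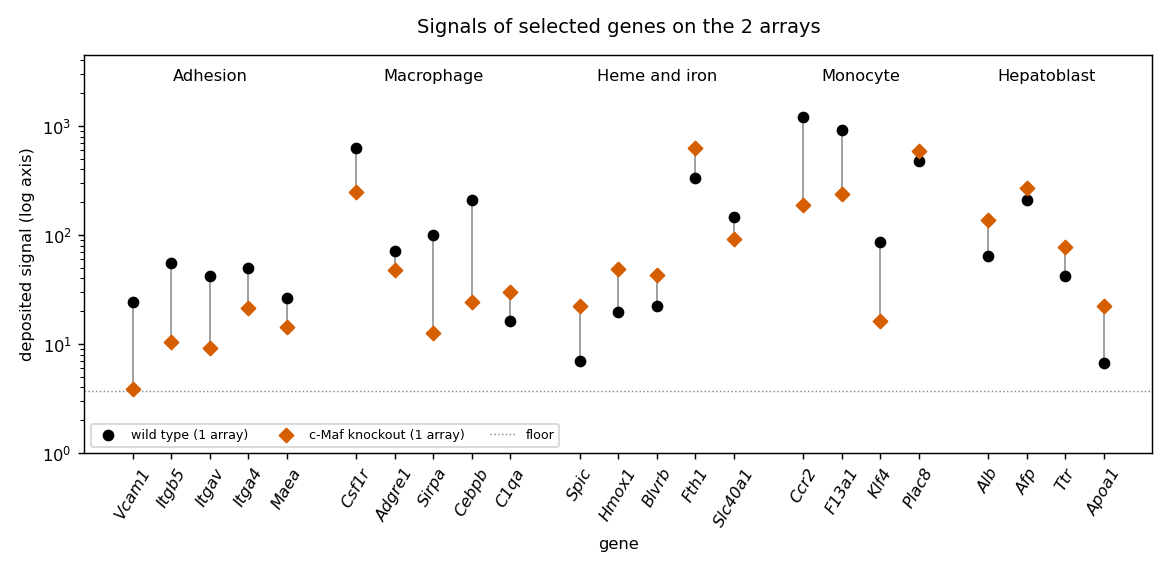
Deposited signal (vertical, log axis) of genes from 5 groups on the wild-type array (black circles) and the knockout array (orange diamonds), 1 array each; the dotted line is the floor of 3.70. Vcam1, Sirpa, Cebpb and Ccr2 are lower in the knockout, while Spic, Hmox1, Fth1, Alb and Apoa1 are higher.

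Erythroid genes had a median of 0.27 level-adjusted and -0.88 as deposited, with 2 of 28 lower and 2 higher, at the 97.7th percentile, which is marginal: it was 97.2 level-adjusted, 95.9 with equal medians, 97.1 without suffixed probe sets, 94.5 with a pseudocount and 74.2 with means over probe sets. Rhd, a red cell membrane protein gene, went from 29.0 to 6.04 (-1.30), Bpgm was at -0.73 and Slc25a37 at -0.67. Hbb-b2 (71.8 to 10.7, -1.64) had probe sets in opposite directions. The 3 embryonic globin genes Hbb-bh1 (-0.46), Hbb-y (-0.58) and Hba-x (0.24) lay within 2-fold (79.0th percentile). Granulocyte genes had 5 of 19 lower and 0 higher (33.3rd percentile), with the antimicrobial peptide gene Camp (1239 to 207, -1.62), Csf3r (-1.11), Ltf (-0.86) and Padi4 (18.2 to below the floor, level-adjusted -1.72) at the low end. Endothelial and stromal genes had 3 of 20 higher and 0 lower, at the 96.5th percentile as deposited and the 98.4th level-adjusted, with Stab2 at 0.14, Reln at -0.14, Pdgfrb at -0.15 and Cdh5 at -0.15.

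**Figure D3:**
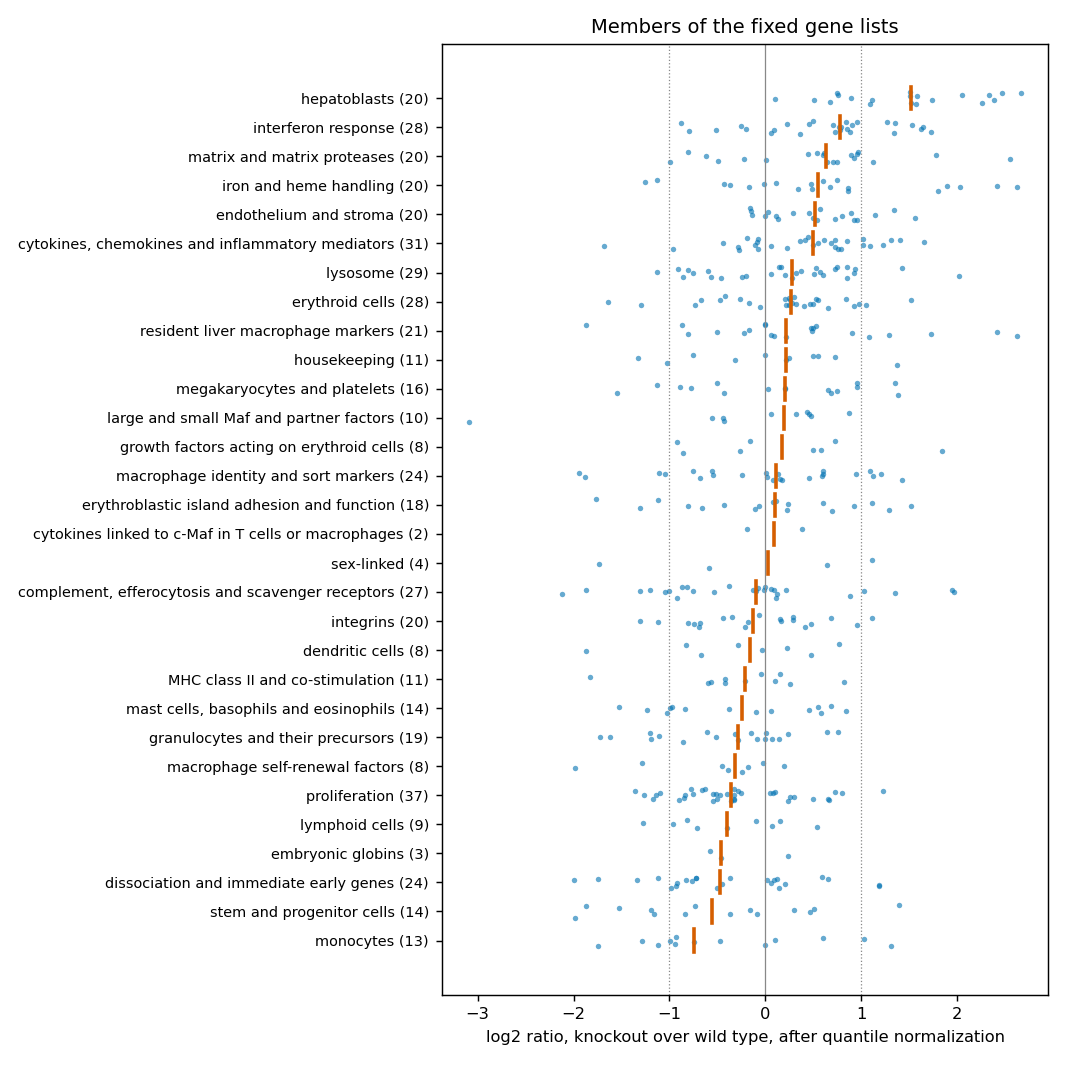
Level-adjusted log2 ratio, knockout over wild type (horizontal), of each measured member of the 30 fixed gene lists (rows, number measured in brackets); points are genes, orange bars list medians and dotted lines 2-fold differences. The hepatoblast list has the highest median, 1.52, and the monocyte list the lowest, -0.74.

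The remaining lists lay inside the central 95% of matched random lists as deposited, except housekeeping genes. Of 10 large and small Maf and partner factors, Maf alone was at least 2-fold lower and 0 were higher (47.7th percentile), with Nfe2 at -0.55, Bach1 at -0.43 and Mafg at -0.44. Of the cytokines tied to c-Maf in other cells, Il10 (5.44 to below the floor) was lower by at least 1.14-fold, Il12a (12.3 to 8.40, 0.39) was within 2-fold (25.2nd percentile), and Il12b was near the floor. The class II gene H2-Aa was 3.54-fold lower (-1.82) and was the 1 lower of 11 antigen presentation genes, while Cd86, H2-DMa and H2-Eb1 were at -0.60, -0.56 and -0.42 (28.7th percentile). Dendritic cell genes had 1 of 8 lower, Flt3, with Tcf4, Btla and Batf3 at -0.67, -0.83 and -0.28 (71.1st percentile). Mast cell, basophil and eosinophil genes had 3 of 14 lower, Hdc (190 to 35.7, -1.23), Kit and Ms4a2 (at least 2.04-fold), and Gata2 was at -0.84 (9.04th percentile). Megakaryocyte genes had 2 of 16 lower, Gp9 (at least 2.93-fold) and Nrgn (at least 2.19-fold), and 2 higher, with Treml1 at -0.89 and Rab27b at -0.77 (85.8th percentile). Lymphoid genes had 1 of 9 lower, Igll1 (-1.27), with Nkg7 at -0.72, Cd79a lower by at least 1.75-fold and Vpreb1 by at least 1.95-fold (13.9th percentile). Erythroid growth factor genes had 1 of 8 higher, Igf2 (28.3 to 46.9, 1.85), whose other probe set went from 5.04 to below the floor, with Igf1 at -0.27, Gas6 at -0.92 and Bmp4 lower by at least 1.81-fold (80.5th percentile).

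Housekeeping genes had a median of 0.21 level-adjusted and -0.48 as deposited, at the 99.9th percentile as deposited but the 91.0th level-adjusted and the 69.8th with probe sets lacking a suffix, with Polr2a (-1.32) and Ywhaz (-1.02) lower, Gusb at -0.76 and Sdha at -0.31. Among sex-linked genes, the X-inactivation RNA gene Xist had signals of 294 in wild type and 39.0 in knockout (-1.74). Its other probe sets were at 113 and 11.4 (-2.20) and at 63.2 and 37.3 (0.41). The Y-linked genes Eif2s3y (13.5 and 10.8, 0.65), Kdm5d (below the floor and 6.05, at least 2.16-fold higher, another probe set lower) and Uty (7.26 and below the floor) were dim, and the list lay at the 59.3rd percentile. In all, 7 of the 30 lists lay above and 1 below the central 95% as deposited. Random lists of unrelated genes would put 1.5 outside it, which is no measure for lists of related and partly shared genes. After level adjustment the immediate early and the stem and progenitor lists also lay below it. The cytokine and endothelial lists then lay above it, and the housekeeping list inside it. The erythroid list (97.2 or 97.8 in separate calculations) and the proliferation list (2.54 or 2) lay at its limits, so their side is not settled.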

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

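With 1 array per genotype no replicate could be left out, and no paired analysis was possible because each group has a single sample. The settings scaled to hybridisation controls, quantile normalization with the brightness limit and quantile normalization with the probe set chosen anew were added after the data were seen. Genes at least 2-fold lower and higher, 5358 and 161 as reported, numbered 2167 and 630 with equal medians, 1203 and 1109 after quantile normalization, 1142 and 1175 with the probe set then chosen anew, and 1108 and 1869 with centred ratios; these scalings shift most ratios upward by construction. Quantile normalization with the brightness limit left 664 and 479. The higher genes were 1461 with the floor at the 25th percentile, 49 with it at the 65th, 259 with a pseudocount, 104 scaled to hybridisation controls and 31 among bright genes, and the lower genes stayed within 1.5 times there. Thresholds of 1.5-, 3- and 4-fold gave 8062 and 527, 2236 and 31, and 957 and 8, and probe sets in place of genes gave 8427 and 293, by construction. The Maf level, a log2 ratio of -3.69, was -2.76 with centred ratios, -5.58 and -2.96 with the floor at the 25th and 65th percentiles, which set its bound, and -1.51 with the mean over probe sets, which brings in dim ones; it stayed negative throughout. Among genes at least 2-fold changed as deposited, directions turned for Oas2 after quantile normalization (0.057 with either choice of probe set), for Hbb-b2 and Rab27b without suffixed probe sets (0.049 and 0.67), and with the probe set chosen anew for Ap2a2 (0.42), Csf1 (0.83) and Hbb-b2 (1.20), where another probe set of the gene stood in. Of 1379 values for named genes, 789 moved by less than 0.65 log2 units, 583 by more and these 7 turned. Genes under 2-fold as deposited changed sign in another 30 values, of 13 genes, and these count by the size of their move. Of 125 genes at least 2-fold changed as deposited, 14 fell short of it with the mean over probe sets (0.62 for Fabp1), 12 with the floor at the 65th percentile, 8 with a pseudocount, 21 with equal medians, 41 with centred ratios and 43 after quantile normalization. Without suffixed probe sets 5 of 105 did, namely Jarid2 (-0.79), Tm9sf2 (-0.58), Mcm5 (-0.68), Hbb-b2 and Rab27b. Of 310 list values, 302 moved by less than the half-width of their matched range. The other 8, as median minus that of matched lists, were cytokines at 0.50 (floor at the 25th percentile) and 0.56 (probe set chosen anew), housekeeping at 0.15 (no suffix), monocytes at -0.14 (mean over probe sets), dendritic cells at -0.63 and -0.46 (floors at the 25th and 65th percentiles), hepatoblasts at 1.16 (pseudocount) and lymphoid cells at -0.76 (floor at the 25th percentile), and the cause was not tested. Signal over background limits the rest: 57.0% of gene probe sets were above the floor on the wild-type array and 42.9% on the knockout array, so a gene dim on both gives no usable ratio.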

Other observations

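The tests below were chosen after the results were seen, except that of the low-oxygen list against matched lists as deposited and that of the further hepatoblast genes, whose members had not been looked up when their predictions were written. Genes of the low-oxygen response and of glycolysis, a group not described above, were higher on the knockout array relative to other genes. Of 37 measured members, 14 were at least 2-fold higher after level adjustment and 0 lower, with a median of 0.84 level-adjusted and -0.08 as deposited. In deposited signal 1 member was at least 2-fold higher, 6 lower and 30 within 2-fold. The list median then stood 0.92 log2 units above its matched lists, against 0.82 for housekeeping genes. Hepatoblast genes were higher on the same array, with 14 of 20 at least 2-fold higher and a level-adjusted median of 1.52. Egln3, an oxygen-sensing prolyl hydroxylase (18.2 to 38.2, level-adjusted log2 ratio 2.16), and its relative Egln1 (23.6 to 32.5, 1.58) were higher. So were the glycolytic genes Ldha (371 to 506, 1.46), Aldoa (262 to 378, 1.60) and Pkm (161 to 200), and Ddit4 (7.25 to 11.2, 1.53). In all, 31 members had ratios above 0 and 6 below. Those below were Pfkfb4 (32.3 to 8.80, -0.83), Slc16a3 (-0.55), Vegfa (10.8 to 4.60, -0.43), Slc2a3 (-0.18), Hk1 (-0.08) and Zfp395 (6.93 to below the floor). These genes were picked from the list after their values were seen.

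The list was drawn up because Bnip3 and Igfbp1, both known targets of the low-oxygen response, were among the largest rises; genes already seen were left out of it. Its median lay at the 100th percentile of matched random lists, as a low-oxygen response across its known genes would need. Smaller shifts of very bright genes did not account for it, since the percentile was also 100 after quantile normalization. A low-oxygen response is a candidate explanation, in the embryo or during sorting, and the design does not separate these from the genotype. With 1 array per genotype, a difference between these particular samples stays open as well. Whether RNA of hepatoblasts, whose transcripts were higher on the same array, contributed to the rise of Igfbp1 or of the low-oxygen list was not tested.

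Hepatoblast transcripts were higher on the knockout array, although a sort for Mac-1 and F4/80 would be expected to remove hepatoblasts. Smaller shifts of dim genes did not account for it, since the list lay at the 100th percentile of random lists matched on signal. A smaller share of macrophages could raise other cell types alike or unequally. The lists bear only on an equal rise, so an unequal rise stays open. Against an equal rise, with each list set against its matched lists, the hepatoblast list lay 1.16 log2 units above the endothelial list. The gap was 1.22 to the erythroid, 1.65 to the granulocyte and 2.23 to the monocyte list (0.78 to 1.64 with means over probe sets). More hepatoblast RNA in the knockout sort may account for the higher hepatoblast transcripts. Of 30 further hepatocyte genes, drawn up after the fixed list was seen, 15 were measured. Their median lay at the 98.96th percentile of matched random lists, with 5 at least 2-fold higher and 1 lower. It was only 0.67 level-adjusted (-0.09 as deposited), against 1.52 (0.66) for the fixed list. A change in the sorted cells or livers of the knockout would need the same and stays open and untested.

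The dimmer signal of most genes on the knockout array was set against its control RNAs. A single scaling factor for the whole array would move controls and genes together, but the median hybridisation control lay 1.17 log2 units above the median gene. Less labelled RNA on the array would lower the poly-A controls too, but these lay 1.41 above the median gene. More degraded knockout RNA would lower 5' signals. Relative to the 3' signals of Actb and Gapdh, these were instead higher by at least 1.02 log2 units. The 3' to 5' ratios of both genes were higher in wild type, and lower integrity of the wild-type RNA was not tested. For Actb the 5' probe set had a log2 ratio of 0.29 and the 3' one -0.85. Less sample RNA per added control transcript before labelling may account for part of the shift, since the poly-A controls lay 0.24 above the hybridisation controls and not below them. It would lower the sample's own transcripts alike. The shift ran from -0.33 in the dimmest signal bin to -1.25 in the brightest. The bins leave out genes below the floor on 1 array, which limits the fall that dim genes can show. The bins therefore cannot decide whether the fall was uniform. Control probe sets had median log2 ratios of 0.90 for Gapdh and -0.04 for Actb, with dimmer ones at -0.33 for Tfrc and -0.75 for Pcx. Less RNA per knockout macrophage and fewer sorted cells would both mean less sample RNA, and neither was tested.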
